A study of Homo sapiens with 3 samples.

How the data were processed

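RNA sequencing of OCI-AML2 R50, a culture of the acute myeloid leukaemia (AML) cell line OCI-AML2 kept in 50 µM cytarabine (Ara-C) and 15% serum per the labels' protocols, was read from 3 libraries. One library was labelled as control and 2 libraries were labelled as treated with romidepsin for 18 h. Each library had its own table of 28837 rows with a gene name and an FPKM value (fragments scaled to gene length and to the mapped fragments of the library), which is the unit the authors deposited, per the file headers. TopHat, Cufflinks, Cuffdiff and the genome build hg19 are named in the submitters' processing notes, while their versions, settings and the gene annotation are not given in the sources used here. The romidepsin dose and the origin of the romidepsin libraries (separate cultures or 1 culture) are likewise not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

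FPKM values were analysed as deposited. The 1770 rows with no gene name held 22.3% of the summed FPKM in the control and 22.1% and 21.1% in the romidepsin libraries; they and the 27 rows named by a bare number (0.075% to 0.0881% of the sum) were left out of all tests. Rows of the same symbol were summed, which concerned 720 of the 25247 symbols. The 744 symbols that join several gene names were kept under the joined name. A gene was tested where at least 1 library reached 1 FPKM, which left 11708 genes, 554 of them joined. A gene under 1 FPKM in the control was therefore tested only if a romidepsin library was higher than the control. In every list, the filter thus tilted such members toward a rise. Changes are differences of log2(FPKM + 1), a scale that understates the change of genes with low values.

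The depth was estimated from the steps between low values, since 1 fragment gives a gene of known length a fixed FPKM. Lengths of genes with a single transcript came from a GENCODE annotation of a different genome build than the one used by the authors, so no coordinates are printed. The steps correspond to about 16700000 fragments for the control and 21400000 and 21600000 for the romidepsin libraries, and they combine depth with the authors' scaling. The control was 0.856 and 0.867 times as deep as the romidepsin libraries by the same steps compared gene by gene, a smaller gap than these totals give, so the depth is approximate. For single-transcript genes with more than 50 fragments, the romidepsin pair differed by 1.16 times the SD that counting alone gives (460 genes), rising to 1.63 times above 5000 fragments (27 genes); with 50 or fewer fragments the ratio was 1.42 (561 genes). No row above 0 held the same value in both files, and the libraries were kept as 2 samples.

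Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) with Benjamini-Hochberg adjustment over the 11708 genes and a threshold of 0.05. The fit had 1 residual degree of freedom, from the romidepsin pair, and a prior of 6.06 degrees of freedom from the other genes; the lone control was assumed to vary like the romidepsin pair. A second rule, with no test, required a difference of at least 2-fold from the control in both romidepsin libraries. Gene lists were described by their median log2 fold change, compared with 10000 random lists of the same size drawn without replacement from 20 bins of mean expression. The two-sided share of random lists as extreme was adjusted over the lists by the Benjamini-Hochberg method, and 0.00085 is the smallest adjusted share obtained, from lists beyond every random list. The lists were first drawn with replacement, which was changed after the results were seen and is kept among the alternatives. The draws without replacement were repeated 10 times with other random numbers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for these steps, and matplotlib 3.10.9 for the plots.

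The groups, tests, gene lists, named genes and most alternatives were fixed before the data were examined. The 36 lists covered HDAC enzymes, genes commonly raised by HDAC inhibitors, leukaemia stem cell surface markers, the LSC17 stemness genes, cytarabine uptake and nucleotide metabolism, drug efflux, pro-apoptotic and anti-apoptotic genes, death receptors, mitosis, DNA replication, CDK inhibitors, homologous recombination, p53 targets, mature monocyte and granulocyte markers, primary granule genes, haematopoietic transcription factors, MYC targets and ribosome biogenesis, histone genes, cytosolic ribosomal proteins, metallothioneins, interferon-stimulated genes, MHC class I and class II presentation, NF-kB targets, the ATF4 stress response, heat shock and ER chaperones, cholesterol synthesis, DNA and histone methylation enzymes (with other chromatin genes), and the respiratory chain. The others were markers of neurons, the erythroid and megakaryocyte lineages, lymphoid cells, epithelium, fibroblasts and the germline. Named genes were the 18 focus genes chosen in advance, the 12 largest rises and 12 largest falls among genes that passed both rules and reached 5 FPKM in the higher condition, and up to 2 members per list and direction with the largest changes. Non-coding and placeholder symbols were passed over among the largest changes. Some members of the lists are not reported here by name. A gene given beyond these is a further member of a fixed list or was chosen after its values were seen.

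Alternatives were other pseudocounts (0.1 and 0.5), no filter or a mean of at least 5 FPKM, quantile normalization, scaling to the same sum or by the median ratio, eBayes without the trend or in its robust form, an adjusted p under 0.01, limma's treat against 1.5-fold, 1.5-fold and 4-fold size rules, and each romidepsin library alone. Keeping the highest row per symbol, keeping only symbols with 1 row and 1 gene, and drawing random lists with replacement were added after seeing the data. The test was tried on simulated data for the 11708 genes of this comparison, with 200 genes changed by known folds. With a control that varied like the pair, it called 92.5% of 67 genes changed by 1.5-fold, all of 67 changed by 2-fold and all of 66 changed by 4-fold, and 0.222% of 11286 unchanged genes. With an added control SD of 0.2 on the log2 scale, 29.8% of 11302 unchanged genes were called, and 0 of them also passed the 2-fold rule. This SD was a chosen value, since no replicate control exists to measure it. A 2-fold difference lies far outside it, so the 0 says nothing of cultures that vary more. The 2-fold rule also left out many genes at its limit. Of the 67 genes changed by 2-fold it kept 10 (14.9%) in the first simulation and 29 (43.3%) in the second. In 10 simulated rounds without a list effect, 5.59% of 340 list medians had an unadjusted share under 0.05, and a list shifted by 0.5 was recovered in 9 of the 10 rounds. These rounds permuted fold changes within the same expression bins as the random lists, so a share near 0.05 was built in. They also broke any shared regulation of list members. The shares treat the genes of a list as independent, and this was not tested.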

Results

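The transcriptome of OCI-AML2 R50 cells was measured with and without romidepsin, a cyclic peptide inhibitor of class I histone deacetylases (HDACs). OCI-AML2 is an established AML cell line, and the culture was maintained in cytarabine, the nucleoside analogue of standard AML chemotherapy. The series title concerns epigenetic drugs and chemoresistant AML cells carrying CD123, the alpha chain of the interleukin 3 receptor. There was 1 control library and there were 2 romidepsin libraries taken at 18 h. The summed FPKM was 790922 in the control and 668773 and 657213 in the romidepsin libraries, and 10838, 11451 and 11458 named genes reached 1 FPKM. Across the 11708 tested genes, the romidepsin libraries differed from each other with an SD of 0.14 on the log2 scale (Pearson r = 0.997 across genes, which are not independent replicates). Each differed from the control with an SD of 0.68 and 0.69 (r = 0.943 and 0.942). Only 12 genes were at least 2-fold apart within the pair, against 1381 and 1380 between each romidepsin library and the control.

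The main comparison asked which transcripts changed after romidepsin. On the log2(FPKM + 1) scale, the largest rise was that of CDKN1A, which encodes the cell cycle inhibitor p21, from 1.51 FPKM in the control to 60.5 ± 2.39 FPKM (SD, n = 2), a 39.9-fold difference. IER3, an immediate early gene, rose from 2.92 to 86.3 ± 0.682 FPKM, and IL1B, which encodes the inflammatory cytokine interleukin 1 beta, rose from 4.79 to 115 ± 3.71 FPKM. The largest fall on this scale was that of MS4A6A, a membrane protein gene of myeloid cells, from 33.9 to 6.06 ± 0.119 FPKM. MYC, the growth-promoting transcription factor, fell from 362 to 117 ± 2.44 FPKM, a 3.08-fold difference.

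Among the other large rises, IFI30, a lysosomal thiol reductase of antigen processing, went from 3.40 to 73.1 ± 1.46 FPKM, and RGS2, a regulator of G protein signalling, went from 3.09 to 54.3 ± 1.27 FPKM. Several of the 12 largest rises started under 1 FPKM in the control, so their FPKM values are given without a fold. SPINK2 rose from 0.278 to 21 ± 0.757 FPKM and TUBB4A, a brain tubulin, from 0.125 to 15.8 ± 0.0828 FPKM. JUP, which encodes plakoglobin, rose from 0.701 to 22 ± 0.961 FPKM, and CD86, a costimulatory ligand of antigen-presenting cells, rose from 0.548 to 19.5 ± 0.5 FPKM. ID2, an inhibitor of basic helix-loop-helix factors, reached 21.2 ± 0.0708 FPKM from 0.681, SERPINB9 17.8 ± 0.461 FPKM from 0.516, and the kinase gene SGK1 17.6 ± 0.0692 FPKM from 0.597. The large falls were smaller in fold. HPDL fell 5.01-fold, PLD6 4.77-fold, LPPR3 4.61-fold and ADI1, an enzyme of methionine salvage, 4.50-fold. The joint row of DUS3L and PRR22 was 4.47-fold lower, and ALX1 was 4.28-fold lower. CCR2, a chemokine receptor of monocytes, fell from 68.1 to 16.3 ± 0.138 FPKM, and CEBPD, a myeloid transcription factor, from 206 to 52.6 ± 0.416 FPKM. PATZ1, the amino acid transporter SLC38A5 and TFAP4 fell 4.06-fold, 3.99-fold and 3.98-fold. Each of these 24 genes had a limma adjusted p of at most 7.12e-07.

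**Figure D1:**
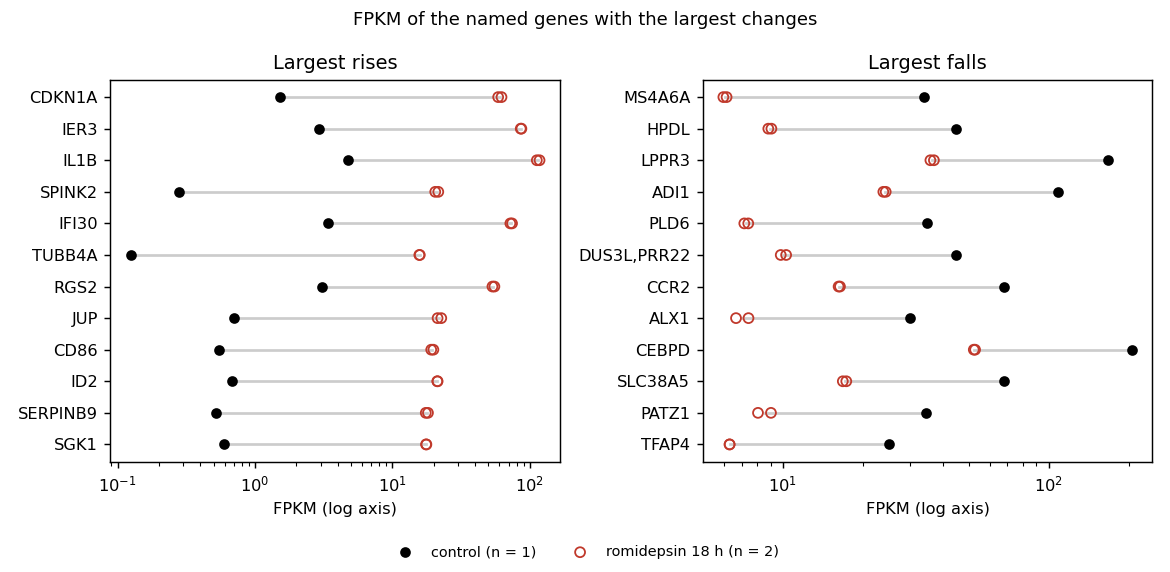
FPKM per library (log axis) of the 12 genes with the largest rises and the 12 with the largest falls on the log2(FPKM + 1) scale, among genes reaching 5 FPKM; filled points are the control (n = 1), open points the romidepsin libraries (n = 2), and grey lines join the control to the romidepsin mean. The romidepsin points lie close together on 1 side of the control for each gene, as for CDKN1A (62.2 and 58.8 against 1.51 FPKM).

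In all, 8953 of the 11708 genes passed the limma test, 4057 higher and 4896 lower. Of these, 870 were at least 2-fold higher and 361 at least 2-fold lower in both romidepsin libraries, and every gene that met the 2-fold rule also passed the test. The difference was at least 4-fold in both libraries for 147 higher and 7 lower genes. The genes at least 2-fold higher had a median of 1.56 FPKM in the control, and 354 of the 870 were under 1 FPKM there. Those at least 2-fold lower had a median of 33.4 FPKM. The scale and filter partly fix this contrast. On this scale a gene under 1 FPKM in the control could not fall 2-fold. Such a gene was tested only where a romidepsin library reached 1 FPKM. In the other direction, 12 of the 361 lower genes had a romidepsin mean under 1 FPKM. The share of called genes rests on the small spread of the pair, and with a single control library a difference between cultures cannot be separated from that of romidepsin. With each library scaled to the same sum, the median of all genes shifted by 0.21 on the log2 scale (from -0.05 to 0.16), called genes were 65.1% higher instead of 45.3%, and the 2-fold genes 87.4% higher (171 lower) instead of 70.7%. The 5 list medians that changed sign with this scaling stayed below the median of all genes. They lay at -0.09 relative to it for anti-apoptotic genes (-0.08 as deposited), -0.04 for homologous recombination (-0.06), -0.1 for transcription factors (-0.12), -0.15 for MHC class I (-0.17) and -0.11 for methylation and other chromatin genes (-0.11).

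**Figure D2:**
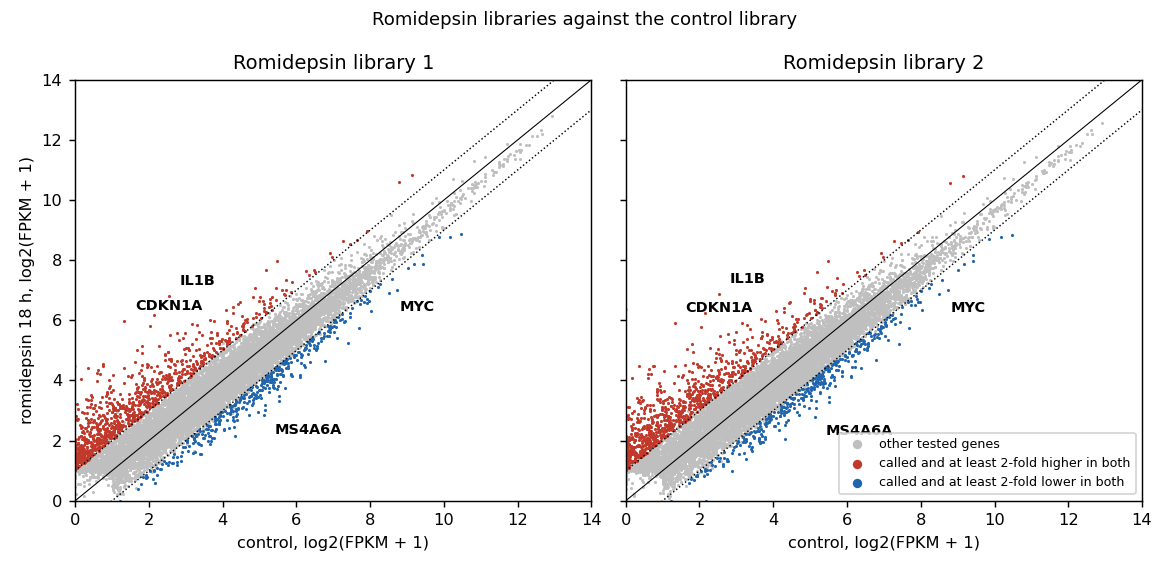
Each romidepsin library against the control, as log2(FPKM + 1) of the 11708 tested genes; the solid line marks equality and the dotted lines 2-fold differences. Red points are the 870 genes called and at least 2-fold higher in both romidepsin libraries, and blue points the 361 lower ones. The red points lie mostly at low control values (median 1.56 FPKM). On this scale, genes under 1 FPKM in the control could not be blue.

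IL3RA, which encodes CD123, was listed at 0 FPKM in all 3 libraries. So were SLC25A6, CD99 and CSF2RA, other genes of the pseudoautosomal region, so an exact 0 cannot be read as absence here. CD34, the surface marker of haematopoietic progenitors, stayed under the 1 FPKM needed for a test (0, 0.133 and 0.187 FPKM), as did ABCB1, a drug efflux pump gene (0, 0 and 0.00895 FPKM). CD38, a surface enzyme of progenitors and plasma cells, was at 30.5 FPKM in the control and 30.8 ± 0.845 FPKM after romidepsin (adjusted p = 0.772), although quantile normalization (adjusted p = 0.047) and scaling to the same sum (adjusted p = 0.00267) called it higher. The adhesion receptor gene CD44 rose from 69.0 to 102 ± 0.840 FPKM. Of the 15 tested members of the stem cell surface list, 10 rose and 2 fell, with a median of 0.37 that stood above the random lists (adjusted share 0.0228; median 0.21 with no filter and 0.60 with scaling to the same sum). CD52 rose from 1.05 to 17.2 and 18.8 FPKM and CD9 from 1.33 to 10.8 and 9.57 FPKM, while CD93 fell from 52.2 to 35.1 and 33.7 FPKM. CD33 also fell, by 0.18, but was not called with quantile normalization (adjusted p = 0.424) and was 0.05 higher with scaling to the same sum (adjusted p = 0.294). Of the LSC17 genes, 7 of 10 rose and 2 fell (median 0.85, or 1.47 with a pseudocount of 0.1, adjusted share 0.0153): AKR1C3 and the methyltransferase gene DNMT3B rose by 2.60 and 1.34 on the log2 scale, and CDK6 and SOCS2 fell by 1.36 and 1.31. The LSC17 risers ZBTB46, ARHGAP22, DPYSL3 and SMIM24 were under 1 FPKM in the control, as were KIT and ITGA6 of the stem cell surface list. They passed the filter only through the romidepsin libraries, so the filter fixed their direction. With a mean of at least 5 FPKM required, which leaves out low-expressed members, the medians were 0.16 and 0.36 and neither list stood apart (adjusted shares 0.151 and 0.245), and the LSC17 list did not with quantile normalization either (median 0.43, adjusted share 0.0739). For each of the 36 lists the counts of members higher and lower were identical adjusted over the list alone and over all genes tested.

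Calls among the HDAC enzymes themselves went in both directions. HDAC1 rose from 137 to 158 ± 4.98 FPKM and HDAC2, its close paralogue, fell from 157 to 117 ± 6.11 FPKM, though the HDAC2 call was lost with quantile normalization (adjusted p = 0.0692) and that of HDAC1 with no filter (adjusted p = 0.0549). The HDAC1 rise was 0.21 on the log2 scale, about the control SD of 0.2 chosen for the simulation, where 29.8% of unchanged genes were called. In the list, 5 of 11 were called higher and 4 lower (median 0.01, adjusted share 0.725), against 7 and 2 with scaling to the same sum. Over all genes, 4057 of 11708 were called higher and 4896 lower, so such a split is not particular to this list. The largest changes were in HDAC11 (log2 1.35, from under 1 FPKM in the control) and HDAC9 (log2 0.87). Among genes commonly raised by HDAC inhibitors, 10 of 12 rose and 1 fell, with a median of 1.35 (adjusted share 0.00085). SAT1, a polyamine catabolic enzyme, rose from 43.4 to 248 and 250 FPKM and TXNIP, a thioredoxin inhibitor, from 21.1 to 97.2 and 96.8 FPKM. HIST1H2BK fell by 0.16, a call lost under 4 alternatives, and was 0.08 higher with scaling to the same sum. Of 18 histone genes tested, 11 rose and 2 fell (median 0.55, adjusted share 0.177), led by HIST1H2BD (log2 1.83). With quantile normalization 5 were higher and 0 lower (median 0.23), while no filter put this list past the threshold (median 0.29, adjusted share 0.0198). Of the metallothioneins, MT2A and the joint row of MT1F, MT1IP and MT1X rose and MT1E fell (median 0.72, adjusted share 0.0823). With no filter the list passed the threshold (0.0491) and the call of the joint row was lost (adjusted p = 0.0848).

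Of the CDK inhibitors, 3 of 7 rose (CDKN1A, CDKN2B and CDKN2D) and 3 fell (median 0.13, adjusted share 0.409). With scaling to the same sum 4 were higher and 1 lower (median 0.37), and with quantile normalization 4 and 2 (median 0.33). Of 24 mitotic genes, 12 rose and 6 fell, against 18 higher and 2 lower with scaling to the same sum and 15 and 2 with quantile normalization. TOP2A rose from 84.7 to 126 and 130 FPKM, and CCNA2 fell from 78.7 to 55.7 and 51.6 FPKM. Their median of 0.11 stood above the random lists (adjusted share 0.0404; median 0.34 with scaling to the same sum), but did not with quantile normalization (median 0.22, adjusted share 0.0776) or without romidepsin replicate 2 (0.0558). Of 27 replication genes, 22 fell and 3 rose, against 11 lower and 7 higher with scaling to the same sum and 15 and 6 with quantile normalization. UNG, a uracil glycosylase, fell by 1.5 and MCM7, a subunit of the replicative helicase, by 1.03. Their median of -0.26 did not stand apart from random lists (adjusted share 0.634) and was -0.03 with scaling to the same sum. BRCA1, a homologous recombination gene, fell from 19.2 to 13.8 ± 0.425 FPKM, and in its list 9 of 22 fell and BLM rose, with a median of -0.11 (adjusted share 0.850). With scaling to the same sum the calls turned, to 11 higher and 3 lower, with a median of 0.12. Of 21 p53 targets, 13 rose and 3 fell (median 0.51, adjusted share 0.00529). BTG2, an antiproliferative gene, rose from 4.43 to 27.6 and 29 FPKM and TP53INP1 by 2.12 on the log2 scale, whereas AEN fell by 1.05, BBC3 by 0.63 and MDM2, the p53 ubiquitin ligase, by 0.26.

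Of the pro-apoptotic genes, 10 of 15 rose and 3 fell (median 0.37, or 0.60 with scaling to the same sum, adjusted share 0.00952). BMF and BIK, which encode BH3-only proteins, rose from 5.04 to 24.6 and 24.1 FPKM and from 11.8 to 37.1 and 41.1 FPKM, and BCL2L11 rose from 15.2 to 19.6 ± 0.613 FPKM. BBC3 and BID fell by 0.63 and 0.45. Anti-apoptotic genes were split, with 3 of 10 higher and 4 lower; the median was -0.13 and the mean 0.08, and with scaling to the same sum 4 were higher and 3 lower with a median of 0.07 (adjusted share 0.944 as deposited). BCL2A1 rose from 4.83 to 25.0 and 26.1 FPKM, and MCL1, read only in a joint row with ADAMTSL4-AS1, from 63.8 to 102 and 98.2 FPKM. CFLAR fell by 0.60. BCL2 fell from 39.5 to 31.4 ± 0.788 FPKM, a call lost with scaling to the same sum (adjusted p = 0.128). Of 12 death receptor and ligand genes, 9 rose and FADD fell. TNF rose from 5.84 to 46.3 and 45.5 FPKM, and the joint row of LOC254896 and TNFRSF10C from 0.403 to 3.22 and 3.04 FPKM. The median of this list was 0.36 (0.57 with scaling to the same sum) with an adjusted share of 0.0487. Only 1 of 10 further draws of the random lists put the list under the threshold, so it is not read as standing apart.

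Markers of mature myeloid cells rose while primary granule genes fell. Of 18 monocyte and granulocyte markers, 12 rose and 5 fell (median 0.89, adjusted share 0.00085; median 0.27 with no filter). ITGAM, which encodes CD11b, rose from 1.53 to 20.9 ± 0.564 FPKM and FPR1, a formyl peptide receptor, from 0.338 to 10.5 and 9.93 FPKM. The joint row of FCGR1A and HIST2H2BF fell by 1.16 and MNDA by 0.84. Of the primary granule genes, made at the promyelocyte stage, 11 of 12 fell and none rose (median -0.81, adjusted share 0.00085). CTSG fell from 1422 to 468 and 461 FPKM and ELANE from 581 to 233 and 236 FPKM. With scaling to the same sum or quantile normalization, 9 of the 12 granule genes were lower and 2 higher, and the median was -0.44 with quantile normalization. Of 21 haematopoietic transcription factors, 7 rose and 11 fell (median -0.17, adjusted share 0.968), but 10 were higher and 8 lower with scaling to the same sum (median 0.07) and 8 and 9 with quantile normalization (median 0.01). BCL6 and GATA2 rose by 1.46 and 1.13, and besides MYC the largest fall was that of SPI1, which encodes PU.1, by 1.01.

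Genes of MHC class II presentation rose together: 9 of 10 tested members rose, each at least 2-fold, and none fell (median 1.60, adjusted share 0.00085; median 1.04 with only symbols in 1 row naming 1 gene). HLA-DMB rose from 2.54 to 28.9 and 29.9 FPKM and HLA-DMA from 6.69 to 32.1 and 36.1 FPKM. CIITA, the transactivator of these genes, rose by 1.21, while CTSS was at 29.4 FPKM in the control and 30.6 and 30.9 FPKM after romidepsin. Reads of HLA genes can be shared between near-identical genes, and HLA-B, HLA-C and HLA-DRB1 were listed at 0 in every library, so the HLA values are uncertain. Of 10 class I presentation genes, 3 rose and 6 fell (median -0.22, adjusted share 0.968), but 4 were higher and 3 lower with scaling to the same sum (median 0.02). PSMB9 rose by 0.38 and HLA-E by 0.35, and PSMB10 fell by 1.35 and the joined symbol of MIR1234, TAPBP and ZBTB22 by 0.72. Of 15 NF-kB targets and chemokines, 10 rose and 3 fell (median 0.96, adjusted share 0.00085; median 0.58 with no filter and 0.62 with only symbols in 1 row naming 1 gene). Besides IER3 and IL1B, the chemokine gene CCL2 rose from 2.07 to 23.7 and 21.8 FPKM; NFKB1 and NFKBIA fell by 0.90 and 0.49, the latter a call lost with no filter (adjusted p = 0.0673). Of 21 interferon-stimulated genes, 13 rose and 4 fell, with IFI6 rising from 27.4 to 110 and 119 FPKM, OASL by 1.94, and ISG15 and MX2 falling by 0.66 and 0.64. Their median of 0.52 had an adjusted share of 0.0286, which was lost under 6 alternatives, among them quantile normalization (0.626, with a median of 0.04 and 8 higher and 2 lower) and leaving out romidepsin replicate 1 (0.0991).

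All 25 MYC target and ribosome biogenesis genes fell, 9 of them at least 2-fold in both libraries (median -0.91, adjusted share 0.00085), and all 25 were also lower with scaling to the same sum. UTP20, which acts in the processing of ribosomal RNA, fell by 1.4 and NOP16 from 112 to 43.6 and 42.3 FPKM. Of 64 cytosolic ribosomal protein genes, 60 fell and RPL39L rose, a call lost with no filter (adjusted p = 0.113); with scaling to the same sum 41 were lower and 1 higher, and with quantile normalization 31 and 8. Their median of -0.39 lay close to the -0.31 of random lists of similarly abundant genes (adjusted share 0.103). This median was -0.15 with scaling to the same sum and -0.09 with quantile normalization. RPS26 fell by 0.99 and RPL7 by 0.76, a call lost under 4 alternatives, and reads of such genes can be shared with their pseudogenes. In the nuclear-encoded respiratory chain 23 of 27 genes fell and none rose (median -0.34, adjusted share 0.845). CYC1 fell by 0.88 and NDUFS3 by 0.68. With scaling to the same sum 14 were lower and 4 higher (median -0.10), and with quantile normalization 12 and 4 (median -0.07). Of 18 genes of the ATF4 stress response, 13 fell and 3 rose (median -0.50, or -0.33 with quantile normalization and -0.26 with scaling to the same sum, adjusted share 0.0178); the tRNA export factor gene XPOT fell by 1.17 and TRIB3 by 0.96, and DDIT4 and PPP1R15A rose by 0.94 and 0.84. This list did not stand apart with a mean of at least 5 FPKM (0.136) or without romidepsin replicate 2 (0.0558). Of 17 chaperone genes, 5 rose and 11 fell (median -0.37, adjusted share 0.471). With scaling to the same sum (median -0.13) or quantile normalization (median -0.08), 6 were higher and 8 lower. HSPA1A and HSPA1B, near-identical genes, rose by 1.74 and 1.18, and HSPH1 and HSPB1 fell by 0.64 and 0.63. Cholesterol synthesis genes rose in 12 of 19 cases and fell in 5 (median 0.29, or 0.51 with scaling to the same sum, adjusted share 0.00989), with MVD and STARD4 rising by 0.73 and 0.48 and FDPS and NSDHL falling by 0.46 and 0.33; the NSDHL call was lost with scaling to the same sum (adjusted p = 0.0795).

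DCK, the kinase that activates cytarabine, was at 24.1 FPKM in the control and 26.4 ± 1.41 FPKM after romidepsin (adjusted p = 0.0827), but 3 scalings called it higher (adjusted p = 0.0283, 0.00149 and 0.0264). SAMHD1, which hydrolyses the active triphosphate, rose from 68.4 to 93.1 ± 0.830 FPKM. TYMS, the thymidylate synthase gene, fell from 263 to 152 ± 3.75 FPKM, and RRM2, a ribonucleotide reductase subunit, rose from 83.6 to 104 ± 2.22 FPKM. In the list of cytarabine uptake and nucleotide metabolism 6 of 21 rose and 14 fell, with a median of -0.27 (adjusted share 0.634). With scaling to the same sum 8 were higher and 9 lower, with a median of -0.02. TK1 and NT5M rose by 0.64 and 0.52, and NT5C and CTPS1 fell by 1.03 and 1. Of 8 efflux genes, 3 rose and ABCC4 fell (median 0.23, adjusted share 0.523), against 6 higher and 1 lower with scaling to the same sum, with the joint row of MVP and PAGR1 rising by 0.97 and ABCA2 by 0.58. The list of DNA and histone methylation enzymes also holds other chromatin and metabolic genes, such as histone acetyltransferases, IDH1 and IDH2. Of its 26 members, 3 rose and 14 fell (median -0.16, adjusted share 0.628), but 11 were higher and 7 lower with scaling to the same sum (median 0.06). Besides DNMT3B, IDH1, an isocitrate dehydrogenase gene, rose by 0.48. KAT2A, a histone acetyltransferase gene, fell by 1.36 and TET1, which encodes an enzyme that oxidizes methylcytosine, by 0.78.

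Some markers of other cell types rose from low values. Of 8 tested neuronal genes, 7 rose and none fell (median 1.48, adjusted share 0.00085, but 0.18 and 0.0491 with no filter): ENO2, a neuronal enolase, went from 0.372 to 10 and 9.19 FPKM and L1CAM from a listed 0 to 3.18 and 3.34 FPKM. The other 19 of the 27 neuronal genes stayed under 1 FPKM. Of 13 fibroblast markers, 6 were tested and 5 of these rose (median 1.59, adjusted share 0.00085). The median was 0.69 with no filter and 3.11 with a pseudocount of 0.1. THY1 went from 1.23 to 8.41 and 8.42 FPKM and COL1A1 from 0.0275 to 2.30 and 2.54 FPKM. COL1A2 was listed at 0 in all libraries. Of 19 erythroid and megakaryocyte markers, 4 were tested and all 4 rose (median 1.11, adjusted share 0.0468). The adjusted share was 0.0518 without romidepsin replicate 2 and 0.0636 with no filter, where the median was 0.74. ITGB3 and ITGA2B rose most, by 1.85 and 1.47, while the globin genes HBA1 and HBB were listed at 0. ENO2, L1CAM, COL1A1, ITGB3 and ITGA2B were under 1 FPKM in the control. They passed the filter only through the romidepsin libraries, so the filter fixed their direction. Of 5 lymphoid markers, 3 rose and NKG7 fell (median 0.47, adjusted share 0.634); PRF1 and CD79A rose by 1.04 and 0.65, calls lost with quantile normalization (adjusted p = 0.119 and 0.379), where 0 were higher and 1 lower (median 0.01). Only 2 epithelial and 2 germline genes were tested, too few for a list median. CLDN7 rose from 0.770 to 3.86 and 3.58 FPKM and PRAME from 3.15 to 6.13 and 6.56 FPKM, while MUC1 and the joint row with SOHLH2 did not pass the test.

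**Figure D3:**
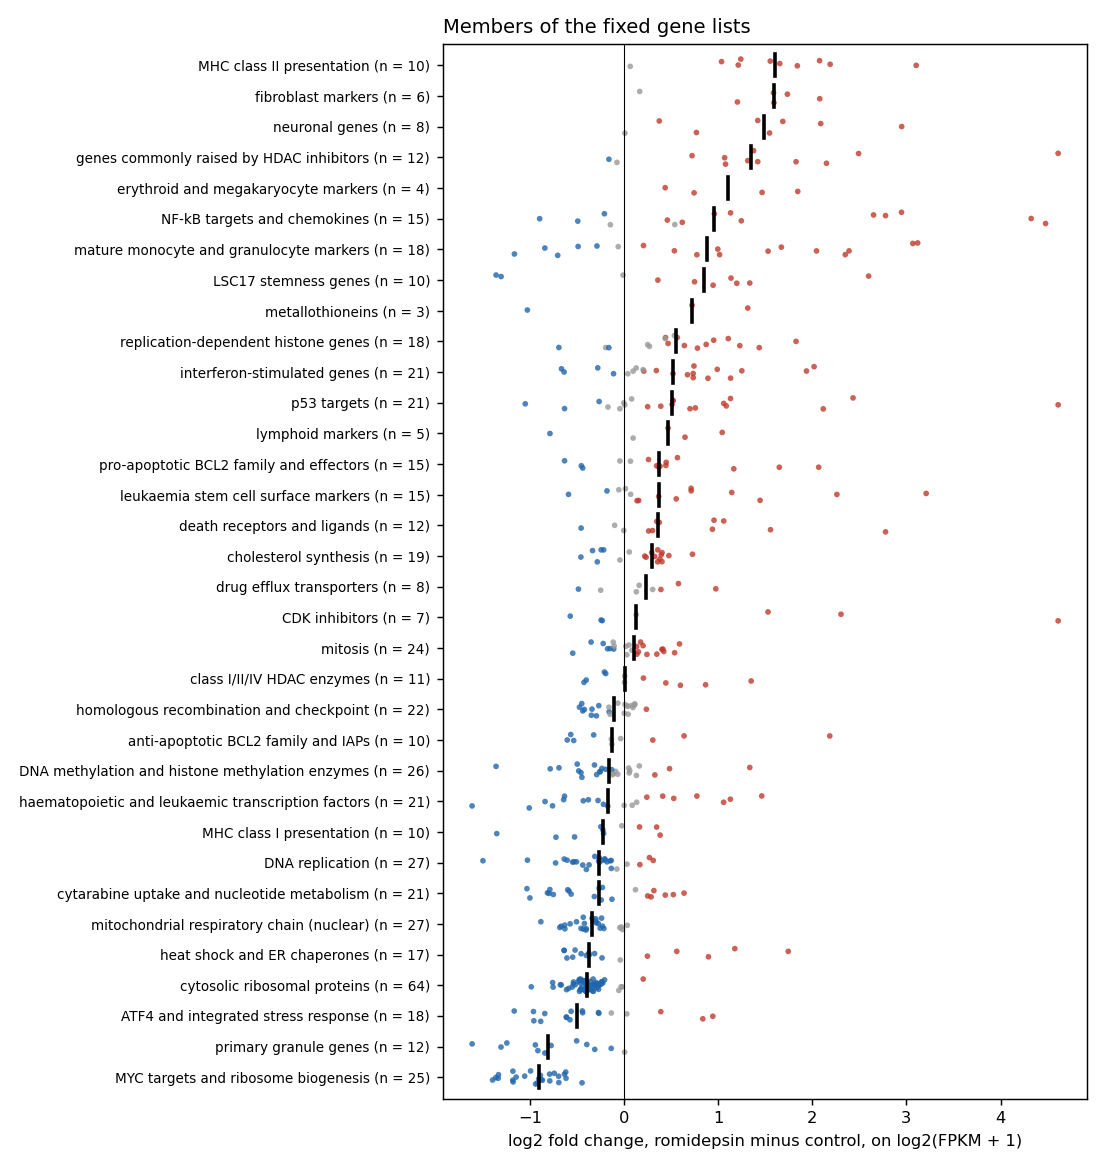
Log2 fold change on log2(FPKM + 1), romidepsin minus control, of each tested member of the lists with 3 or more tested members; red points were called higher, blue points lower and grey points neither, black bars are list medians, and n counts members. Medians run from -0.91 for MYC targets and ribosome biogenesis to 1.60 for MHC class II presentation; with scaling to the same sum, which shifts the median of all genes by 0.21, 5 medians near 0 change sign (anti-apoptotic genes, homologous recombination, transcription factors, MHC class I, and methylation and other chromatin genes) and stay below the median of all genes.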

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

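The tests in this part were all chosen after the results were seen. Rows with no gene name, which no comparison of the report uses, also held differences between the groups: of 890 such rows reaching 1 FPKM, 22 were at least 2-fold higher and 46 at least 2-fold lower in both romidepsin libraries than in the control. The row with the widest gap within the romidepsin pair read 3583 FPKM in the control and 10812 and 2410 FPKM in the romidepsin libraries.

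IL3RA, the CD123 gene named in the series title, was listed at 0 in all 3 libraries, and the values of its whole region appear to be lost. All 26 pseudoautosomal symbols in the tables, some of them non-coding, were under 0.05 FPKM in all 3 libraries, 23 of them at exactly 0. Of 699 other coding genes of the X chromosome, 291 were under 0.05 FPKM in all 3 libraries, and 322 (46.1%) reached 1 FPKM. A candidate explanation is that reads placed equally well on the X and Y copies of this region were dropped by the authors' processing; the test shows the loss, not the step that caused it. Whether romidepsin changed IL3RA therefore stays open in these data.

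Many genes with low control values rose, 354 of them from under 1 FPKM. Genes under 1 FPKM in the control could pass the filter and the 2-fold rule only by rising. Uniform background reads in the romidepsin libraries are argued against by 368 olfactory receptor genes, which averaged 0.00221 FPKM in the control and 0.00708 and 0.0093 FPKM there, higher but far below a median rise of 2.45 FPKM in the raised genes. Within the romidepsin pair, at most 4 genes were under 1 FPKM in 1 library and at least 2-fold higher in the other. Between the control and each romidepsin library there were 403 and 397 such genes. This argues against counting noise at the depth of the pair as the whole cause. The 2 romidepsin libraries were about equally deep (ratio 1.005), while the control was 0.856 and 0.867 times as deep as they were. What the shallower control missed was therefore not tested. An earlier Poisson test on the raised genes was dropped because their selection fixed its outcome. A response to romidepsin, such as release of silenced genes, may account for the rises and stays open as a hypothesis, as does a difference between the lone control culture and the treated ones.

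Markers of fibroblasts and neurons rose among these genes. RNA of fibroblasts would bring their abundant collagens along. The highest of COL1A2, COL3A1, COL5A1, COL6A1 and COL6A3 was 0.0171 FPKM in a romidepsin library, against a mean of 2.42 FPKM for COL1A1. But COL1A2, COL3A1 and COL6A1 were listed at 0, and the compared collagens were picked from list members under 1 FPKM. That leaves COL5A1 and COL6A3, whose low values do not exclude RNA of fibroblasts. In the romidepsin libraries, SNAP25, STMN2, SYT1, GAP43, CHGB, SCG2, SCG3 and NEFH were at most at 0.0718 FPKM. ENO2 had a mean of 9.61 FPKM there. But these neuronal genes were picked after seeing the values, from list members under 1 FPKM. TUBB3 of the same list rose from 0.357 FPKM to a mean of 2.63 FPKM. It is also on the list of genes commonly raised by HDAC inhibitors, so its rise does not decide the question. Because the compared genes were picked by their low values, RNA of neurons is not excluded. An exact 0 can be a failed estimate, but COL5A1, COL6A3, CHGB, SCG2, SCG3 and NEFH had values above 0 in a library. Expression of the raised markers in the leukaemia cells after romidepsin may explain the rise and was not tested.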

How the results depend on the processing

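The control is a single library, so no alternative tests how far control cultures vary, and values listed at 0 limit what can be said of IL3RA and the HLA genes at any depth. No paired analysis was possible because there is 1 control library, so the groups share fewer than 2 replicate numbers. Alternatives planned for counts (DESeq2 size factors, TMM and a count filter) were not run because the tables hold FPKM, and leaving out a romidepsin library leaves no residual degree of freedom for a count of calls.

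The count of called genes fell by construction when a size was added: to 2217 (1256 higher, 961 lower) against 1.5-fold with treat, and to 1231 (870 higher, 361 lower) with the 2-fold rule. Scaling to the same sum left 3059 lower calls, and the higher share of calls was 65.1% instead of 45.3%. The 2-fold count was 1851 (1308 higher, 543 lower) with a pseudocount of 0.1 and 772 (463 higher) with a mean of at least 5 FPKM, where fewer genes were tested and 60% were higher. It was 3366 (1830 higher, 1536 lower) at 1.5-fold and 154 (147 higher, 7 lower) at 4-fold. Scaling to the same sum left 171 lower genes, with 87.4% higher instead of 70.7%. Without 1 romidepsin library it was 1380 or 1381. All other alternatives stayed within 1.5 times the counts as deposited. Of the 870 higher and 361 lower genes, quantile normalization kept 594 and 262, and scaling by the median ratio 870 and 306. None of the 9 alternatives that changed values or genes took a gene from 2-fold higher to 2-fold lower or back. They shifted the median of all genes by at most 0.21 on the log2 scale. Such a turn was therefore unlikely in advance, and its absence is no test of direction.

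With a mean of at least 5 FPKM, 9 lists stood above the random lists instead of 15. Fewer members were tested there, and some medians were also smaller, such as 0.28 instead of 0.52 for interferon-stimulated genes. The 2 were not separated. Drawing the random lists with replacement left 14 lists above them, without the death receptors. The adjusted share of the death receptors ran from 0.0256 to 0.0966 over the alternatives and missed the threshold in all but quantile normalization. Over all list medians and alternatives, 26 calls were lost, 2 were gained and none reversed. Of the named genes, HIST1H2BK (0.0755) and CD33 (0.0537) changed sign with scaling to the same sum, where neither was called (adjusted p = 0.244 and 0.294; over the alternatives, those of HIST1H2BK reached 0.888 and those of CD33 0.424). Over all named genes, 22 calls were lost without a change of sign, some of them for HIST1H2BK and CD33, and 5 were gained. The cause of the changes not attributed here was not tested.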

Other observations

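The genes and tests in this part were chosen after the data were seen, and the values are given without an explanation. Symbols were grouped by their leading letters into 183 families of 8 or more tested genes, and each was tested for genes at least 2-fold higher or lower against 11154 tested genes with a single symbol (Fisher's exact test, Benjamini-Hochberg over 366 tests). Symbols beginning with HLA had 6 of 9 members at least 2-fold higher, where 0.683 were expected (adjusted p = 0.00475), all of them class II genes already in the fixed list. Symbols beginning with S and a number had 7 of 16 higher (1.21 expected, adjusted p = 0.0162), 6 of them S100 genes, among them S100A8 and S100A9. Symbols beginning with CD and a number had 12 of 51 higher (3.87 expected, adjusted p = 0.0414), among them CD36, CD40, CD69, CD82 and CD86. The RGS genes, with 4 of 10 higher, did not pass (adjusted p = 0.250).

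Some abundant genes rose outside the fixed lists. LGALS1, which encodes galectin 1, rose from 439 to 1540 ± 18.5 FPKM (SD, n = 2), FSCN1, an actin bundling gene, from 35.2 to 199 ± 5.23 FPKM and LMNA, which encodes lamins A and C, from 28.2 to 135 ± 0.252 FPKM. CCNA1, the germline and leukaemia cyclin, rose from 4.91 to 44.1 ± 0.795 FPKM, while CCNA2 fell. HMOX1, which encodes haem oxygenase 1, went from 0.0366 to 7.97 ± 0.388 FPKM. CX3CR1, a chemokine receptor gene, rose from 7.56 to 31.6 ± 0.0135 FPKM. MS4A3, a gene of granulocyte progenitors, fell from 426 to 127 ± 0.129 FPKM, and DEFB1, which encodes a defensin, from 688 to 241 ± 11.9 FPKM. TERT, the telomerase catalytic subunit, was at 5.76 FPKM in the control and fell to 1.47 ± 0.0666 FPKM. Every gene of this paragraph passed the limma test.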
